A study of Mus musculus with 40 samples.

How the data were processed

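Expression was measured by poly(A) RNA sequencing of mouse mammary glands in 31 libraries that fall into 12 groups, of which 5 held 2 libraries and 7 held 3. Another 9 samples of the series were chromatin immunoprecipitation libraries, 3 of them inputs, and these were not analysed here. Groups were taken from the sample labels.

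The deposited table holds FPKM, fragments per kilobase of transcript scaled to the mapped fragments of a library, for 22552 genes in 12 columns, and each column is the authors' value for a whole group. Each gene thus has 1 value per group, with no replicate values, so no SD, n or p-value can be attached to any of them. How the libraries of a group were combined is not given in the sources used here. CASAVA, Trim Galore, FastQC, BWA, Bowtie, TopHat, Cufflinks, Cuffdiff and HOMER are named, with the mouse build mm9 and no versions, per the submitters' processing notes. The notes do not say which of these tools served the RNA libraries. Read depth is unknown from these values. Steps of single reads were looked for among genes below 0.05 FPKM in both of 2 groups. The most common ratio between the groups covered 2.11% of 1282 such genes in the control and Ezh2 KO groups at p13, so whole reads could not be recovered. None of 14 ubiquitously expressed genes was listed at 0 in any group, and a gene given as 0 is described as listed at 0.

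A linear model with limma on log2 values was planned before the data were examined. With 1 value per group it could not be fitted. The fallback written with that plan was used instead. Differences between groups were computed as log2(FPKM + 1) of the first group minus that of the second, a scale that understates the difference of low genes, and folds are ratios of FPKM without the pseudocount. Genes were kept where at least 1 group reached 1 FPKM, which left 14273 genes. Genes with a difference of 1 or more in size were counted. That threshold was set after the table was seen to hold 1 value per group, and the count is a description of these pooled values, not a test. For each of 24 gene lists fixed with the same plan, the median difference of the members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The resulting percentile describes these values and is not a p-value. The 24 lists cover milk proteins, milk fat and lipid synthesis, alveolar transport, prolactin and STAT5 signalling, Polycomb proteins and targets, cell type markers, and stress, immune, clock and hormone responses. Correlations were computed across genes, which are not independent replicates, and carry no p-value.

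The fixed rule for named genes took Ezh2 and Ezh1 first. For each genotype or prolactin comparison it then took the 8 largest differences in each direction among genes with at least 5 FPKM in a compared group, and for each list it took 2 to 4 members with large differences. Applied to all genes, this rule made 224 picks over 14 comparisons of 2 groups, in which a gene can be picked more than once. Of these picks 170 were of small RNA genes and 171 of genes listed at 0 in 1 of the 2 groups. Snord37, a small nucleolar RNA at 46.1 FPKM in the p13 Ezh2 KO group and listed at 0 in control, is an example. The named genes therefore come from the same rule applied to protein-coding genes, a choice made after the values were seen. A few genes that this rule takes are not reported here. Gene types came from a RefSeq gene table on the GRCm38 assembly, matched by symbol for 20004 genes and by synonym for 2339, with 209 unmatched. Since the files use mm9, no coordinates are given.

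Computations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data in which 200 genes differed by known folds, with added noise of 0.1 (SD, log2). For the p13 comparison of Ezh2 KO with control, on 14245 genes, 100 of 100 genes altered 4-fold and 100 of 100 altered 3-fold passed the threshold. Only genes with at least 5 FPKM were altered, where such folds pass nearly by construction. The test thus checks the code, and its noise does not stand for variation between mice. The alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 5 FPKM, rescaling each group to a common sum, to a common upper quartile or to a common sum without milk proteins, and 3 settings chosen after seeing the data, which were a threshold of 2, protein-coding genes alone and a common sum without milk, muscle and erythroid genes.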

Results

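Gene expression was measured in mammary glands of virgin mice and of mice on days 13 (p13) and 18 (p18) of pregnancy. Besides controls, the labels give knockout (KO) of Ezh1, of Ezh2, and of Ezh2 with a single Ezh1 allele. EZH1 and EZH2 are the alternative catalytic subunits of Polycomb repressive complex 2, which methylates lysine 27 of histone H3. At p13 there were 3 libraries in each of the control, Ezh1 KO, Ezh2 KO and Ezh1 heterozygous Ezh2 KO (Ezh1 het Ezh2 KO) groups. At p18 there were 3 in each except Ezh1 KO, which had 2. Virgin glands at 12 weeks gave 4 groups of 2 libraries, from control and Ezh2 KO mice before and 2 h after prolactin at 5 µg per g. In the prolactin design the untreated gland was removed first and the opposite gland of the same mouse was taken after the injection, so time, anaesthesia and surgery came with the hormone. Every value below is the authors' pooled FPKM for a group. There are no replicate values, no difference has a replicate check, and read depth is unknown. The summed FPKM of a group ran from 581531 to 1151971, and milk protein genes made up 48.1% of the sum in the p18 control and 2.17% in the p13 control.

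The targeted genes were examined first. Ezh1 stood at 14.7 FPKM in the p13 control and 1.06 in the p13 Ezh1 KO group, a 13.9-fold lower value, and at 7.37 and 0.627 in the same groups at p18, 11.8-fold lower. With a single Ezh1 allele and Ezh2 KO it was 6.17 at p13 and 3.41 at p18, and in Ezh2 KO with both alleles 9.50 and 7.34. Ezh2 was not lower in the p13 group labelled Ezh2 KO, at 13.7 FPKM against 12.9 in control, while the Ezh1 het Ezh2 KO group had 9.54. At p18 Ezh2 was 10.0 in control, 6.41 in Ezh2 KO and 6.24 in Ezh1 het Ezh2 KO. In virgin glands Ezh2 was 5.55 in the group labelled Ezh2 KO against 4.98 in control without prolactin, and 4.64 against 6.74 after it. The values cover the whole gene in whole tissue, and which exons the deletion removes is not given in the sources used here. They therefore check the Ezh1 KO labels but leave the Ezh2 labels unchecked, and Ezh2 KO below means the group labelled so. Nor do they show which cells of the tissue carry the Ezh2 deletion. The list of 13 PRC2 subunits and H3K27 demethylases had no member 1 log2 unit or more from control in Ezh2 KO at p13 (median 0.10, and -0.016 with a common sum of FPKM) or p18 (median -0.04). Of 28 Polycomb target genes, 18 stayed below 1 FPKM in every group. Of the other 10, 2 were lower by that much in Ezh2 KO at p13 and 1 was higher at p18. Cdkn2a, which encodes cell cycle inhibitors, was 8.37-fold higher in Ezh1 het Ezh2 KO than in control at p13, at 5.07 against 0.606 FPKM.

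The control glands were compared across the stages, and whether they give the course of normal pregnancy was not tested. Fasn, the fatty acid synthase gene, stood at 617 FPKM in virgin control without prolactin, 39.9 in the p13 control and 315 in the p18 control. The other p13 groups had 299 to 772. From virgin to p13, Csn2, which encodes beta-casein, went from 0.443 to 5570 FPKM and Csn1s2a from 0.403 to 2153. Of 15 milk protein genes 12 were higher by at least 1 log2 unit and 1 was lower (median 3.31). All 18 proliferation genes were higher at p13 (median 3.37), among them Top2a, a DNA topoisomerase, at 29.2 against 0.989 FPKM. All 10 basal and myoepithelial markers were also higher (median 2.06), including Krt5 at 78.2 against 14.2. From p13 to p18, Wap, the whey acidic protein gene, went from 24.99 to 38474 FPKM, Lalba, whose product is a subunit of lactose synthase, from 5.53 to 2785, and Csn2 to 145905. At p18 14 of 15 milk protein genes were higher (median 4.88), as were 12 of 15 milk fat and lipid synthesis genes (median 2.43) and 11 of 12 interferon response genes (median 1.92). All 13 adipocyte markers were lower at p18 (median -2.57), with Lep, which encodes leptin, at 21.7 against 452 FPKM. All 12 skeletal muscle markers were also lower (median -7.36). These genes made up 1.56% of the summed FPKM in the p13 control, 0.400% in p13 Ezh1 KO and at most 0.0650% in every other group, and Ckm, the muscle creatine kinase, was at 1404 FPKM in the p13 control and 8.13 in virgin control. In all, 1695 genes differed by the threshold between virgin and p13, 1301 of them higher at p13, and 3231 between p13 and p18, 507 of them higher at p18. The median over all genes was 0.17 and -0.46, and between p13 and p18 the median of the ubiquitously expressed genes was -0.67. Between p13 and p18 the split was 327 higher and 6508 lower with a common sum (shift -0.46), 901 and 1424 with a common upper quartile (shift 0.42), 756 and 1718 with a common sum without milk proteins (shift 0.30), and 730 and 1785 without milk, muscle and erythroid genes (shift 0.27).

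At p13 the milk genes were higher in Ezh2 KO than in control. Of 15 milk protein genes, 14 were higher by at least 1 log2 unit and none was lower (median 2.90, percentile 100). Csn1s2a stood at 32011 against 2153 FPKM, Glycam1, a mucin-like milk protein, at 12834 against 396, Lalba at 99.4 against 5.53 and Wap at 291 against 24.99. Of 15 genes of milk fat and lipid synthesis 9 were higher (median 1.52), with the lipid droplet protein gene Cidea at 50.3 against 3.28 and Fasn, the fatty acid synthase gene, at 299 against 39.9. Of 10 transport genes of alveolar cells 4 were higher (median 0.77), including Folr1, a folate receptor, at 56.2 against 11.1. Of 12 luminal epithelium markers 1 was higher past the threshold (median 0.70), and Krt19 was at 555 against 337. Other high genes were Ucp1, the brown fat uncoupling protein, at 65.5 against 0.499, Lao1, an amino acid oxidase, at 52.0 against 1.68, and Pigr, the receptor that carries IgA into milk, at 55.3 against 2.91. Gm5506 was at 41.5 against 0.480 and is uncertain, since retrocopies share reads with their parent genes. Of 12 interferon response genes 10 were higher (median 1.497), with Ifit1 at 34.3 against 7.47. Of 13 adipocyte markers 10 were lower (median -1.35), with Adipoq, which encodes adiponectin, at 739 against 2780, and 5 of 10 macrophage markers were lower (median -0.85). The 8 lowest genes were all skeletal muscle genes: Ckm, Tnnt3, Atp2a1, Myh4, Tnni2, Acta1, Tnnc2 and Mylpf, each from 715 to 2211 FPKM in control and from 0.701 to 5.36 in Ezh2 KO. All 12 muscle markers were lower (median -8.42), as were 4 of 5 erythroid genes (median -2.35). In total 378 genes were higher and 940 lower. The muscle and red cell transcripts of the control group enter every p13 comparison with it.

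**Figure D1:**
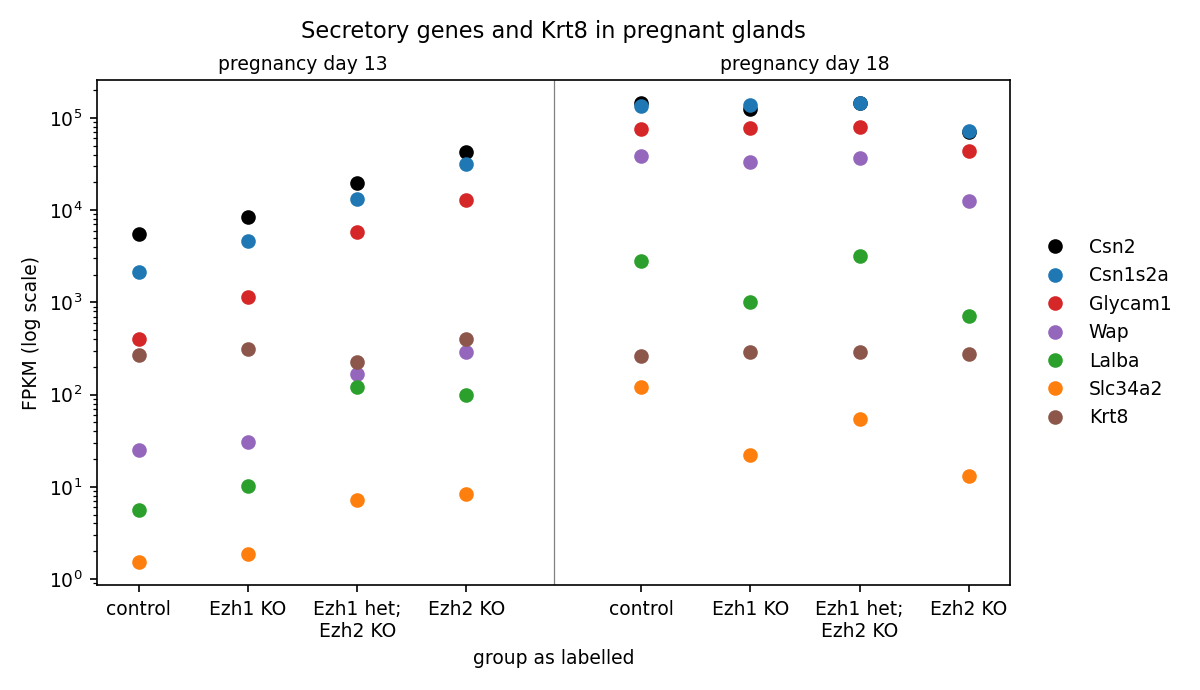
FPKM on a log axis for 6 secretory genes and the luminal keratin gene Krt8 in the 8 pregnant groups, with 1 pooled value per point and no error bars because the table holds none. Csn2 is at 5570 in the p13 control and 42713 in p13 Ezh2 KO, and at 145905 in the p18 control and 70592 in p18 Ezh2 KO.

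At p13 the Ezh1 KO group lay closer to control. Of 15 milk protein genes 2 were higher past the threshold (median 0.41, percentile 100), with Glycam1 at 1151 against 396 FPKM. Lipid synthesis genes were higher by more, 6 of 15 (median 0.92), led by Fasn at 435 against 39.9 and Thrsp, a regulator of lipogenesis, at 788 against 108. The genes with the largest higher values were mostly liver transcripts: Apoa2 at 143 against 1.26, Fabp1 at 74.3 against 0.322, Ttr at 24.6 against 0.0702, Apoa1 at 16.0 against 0.0370, Hamp at 13.9 against 0.0478, Mup3 at 31.9 against 1.58 and Alb, the albumin gene, at 110 against 8.78. Gm5506 was at 39.6 against 0.480. Among the lowest genes were Mrgprg at 0.858 against 20.8, Myh1 at 4.32 against 61.0, Myl2 at 0.581 against 10.5, Sfrp5 at 19.7 against 152, Vnn1 at 1.98 against 20.7 and Ezh1 itself. Hba-a1 was listed at 0 against 1320, which is uncertain because the alpha-globin copies are nearly identical. Adipocyte markers had a median of -0.81 with 4 of 13 lower, all 12 muscle markers were lower (median -2.14), endothelial markers had a median of -0.59 with none of 7 past the threshold, and 3 of 12 interferon genes were higher (median 0.88). In total 300 genes were higher and 325 lower. The majority depended on the setting, with 370 and 328 under a common sum, 319 and 277 with a common sum without milk proteins, 141 and 70 at a threshold of 2, and 103 higher and 291 lower among protein-coding genes.

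The p13 Ezh1 het Ezh2 KO group had higher milk protein genes than control. Of 15 milk protein genes 10 were higher than in control (median 1.75), with Lalba at 121 against 5.53 FPKM and Glycam1 at 5755 against 396, and 10 of 15 lipid synthesis genes were higher (median 1.91), with Fasn at 772 against 39.9, Thrsp at 1515 against 108 and the fatty acid elongase gene Elovl6 at 90.5 against 6.15. All 12 interferon response genes were higher (median 1.88), and the interferon-induced Gbp1 was at 11.1 against 0.224. All 14 lymphocyte markers were higher (median 1.88), with the B cell receptor gene Cd79a at 10.2 against 0.755. A set of 10 lymph node genes, assembled after the values of the lymphocyte markers were seen, had a median of 0.81, with Fcer2a at 2.04 against 0.152 and Pax5 at 0.888 against 0.0243. Luminal markers were close to control (median -0.03). Hba-a2 was at 174 against 0.0620 and Hba-a1 at 0.340 against 1320, a pair to be read together as uncertain copies, and Gm5506 was at 18.4 against 0.480. The other 7 lowest genes were the muscle genes Ckm, Tnnt3, Atp2a1, Acta1, Tnnc2, Myh4 and Tnni2. In total 446 genes were higher and 456 lower than in control. The majority depended on the setting, with 538 and 490 under a common sum, 517 and 389 with a common sum without milk proteins, and 291 higher and 411 lower among protein-coding genes. Against Ezh2 KO, 399 genes were higher and 95 lower. In that comparison 6 of 15 milk protein genes were lower (median -0.78), 3 of 10 basal markers (median -0.89) and 3 of 6 brown fat markers (median -1.12), with Ucp1 at 1.88 against 65.5. Proliferation genes had a median of -0.62 with none of 18 past the threshold. Lymphocyte markers were higher (median 1.63, 13 of 14), and so were Cxcl13, a B cell chemokine, at 15.5 against 0.831, Pi16 at 117 against 19.9, Marco at 5.15 against 0.302, Myoc at 5.27 against 0.458 and Hbb-b2 at 156 against 35.5. Lower genes included Lars2 at 39.1 against 489, Chi3l1 at 9.39 against 42.1, Cpt1b at 1.42 against 6.89, Tspan8 at 3.32 against 12.2, Cox7a1 at 20.2 against 58.4 and Fcgbp at 14.9 against 43.5.

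At p18 the milk genes were lower in Ezh2 KO than in control. Of 15 milk protein genes 8 were lower by at least 1 log2 unit and none was higher (median -1.01, percentile 0). Csn2 stood at 70592 against 145905 FPKM, Wap at 12683 against 38474, Lalba at 717 against 2785 and Lpo, which encodes lactoperoxidase, at 4.69 against 37.1. Of 10 alveolar transport genes 7 were lower (median -1.26), with the phosphate transporter gene Slc34a2 at 13.2 against 122 and the calcium pump gene Atp2b2 at 0.341 against 7.84. Of 15 milk fat and lipid genes 7 were lower (median -0.91), with Btn1a1, a milk fat globule protein gene, at 175 against 707 and Cidea at 59.7 against 277. The other lowest genes were Pip at 0.397 against 13.8, Tc2n at 2.55 against 27.2, D830030K20Rik at 1.84 against 20.03, Tnnt3 at 0.246 against 6.76 and the lipid transporter gene Mfsd2a at 1.30 against 12.8. Luminal markers were near control (median 0.13, none of 12 past the threshold). Interferon response genes were lower, 7 of 12 (median -1.06), with Irf7 at 50.7 against 161. Adipocyte markers were higher, 7 of 13 (median 1.04), with Lep at 204 against 21.7 and Adipoq at 1198 against 333, as were 4 of 6 brown fat markers (median 1.35), with Ucp1 at 32.4 against 0.964. Most of the highest genes were those of red cells: Beta-s at 3376 against 85.7, Hbb-b1 at 160 against 4.34, Hba-a1 at 985 against 36.2, Alas2, the erythroid heme synthesis enzyme, at 98.4 against 3.39, and Hbb-b2 at 204 against 10.4. Of the 5 erythroid genes in the list, which leaves out Beta-s, 4 were higher (median 4.50). Gm5506 was at 41.0 against 0.311. In total 340 genes were higher and 306 lower. With the FPKM of every group rescaled to a common sum the split was 650 higher and 183 lower, and the median over all genes shifted by 0.22. Without milk proteins in the sum it was 306 higher and 367 lower, the opposite majority.

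The p18 Ezh1 KO group was also below control in part of the secretory genes. Of 10 transport genes 5 were lower (median -0.97), with Slc34a2 at 22.4 against 122 FPKM and Atp2b2 at 0.879 against 7.84, and 7 of 15 milk fat and lipid genes were lower (median -0.92), with Cidea at 63.7 against 277. Milk protein genes had a median of -0.44, with 2 lower and 1 higher of 15. Pip at 1.197 against 13.8, Mfsd2a at 1.69 against 12.8, Tc2n at 5.48 against 27.2, Deptor at 5.41 against 25.8 and Ezh1 completed the lowest genes. Gm5506 was at 23.1 against 0.311. Higher genes were Hbb-b1 at 50.6 against 4.34, Beta-s at 572 against 85.7, Hba-a1 at 239 against 36.2, Hbb-b2 at 48.1 against 10.4, Calca, the calcitonin gene, at 61.5 against 11.9, Pnmt at 6.37 against 0.688 and Pvalb at 12.2 against 2.24. Muscle markers were higher, 11 of 12 (median 1.52), adipocyte markers had a median of 0.81 with 3 of 13 higher, and fibroblast markers had a median of -0.66 with 1 of 7 lower. In total 173 genes were higher and 198 lower. A common sum without milk proteins gave 130 higher and 328 lower and shifted the median over all genes by -0.12, and one without milk, muscle and erythroid genes gave 130 and 327. At a threshold of 2 the split was 60 and 49.

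In the p18 Ezh1 het Ezh2 KO group, milk protein genes lay near control (median -0.06, 1 higher and 1 lower of 15), with Csn2, Wap and Lalba not among the genes past the threshold. Transport genes had a median of -0.08 with 1 of 10 lower. Lymphocyte markers were higher, 10 of 14 (median 1.12), with Cd79a at 8.70 against 0.469 FPKM and Igj, the antibody joining chain, at 113 against 22.1, and the lymph node genes had a median of 0.32. Gbp1 was at 12.4 against 0.536, Slpi at 67.1 against 10.3, Marco at 5.09 against 0.0888, Bex4 at 12.1 against 1.89, Pglyrp1 at 64.6 against 13.9 and Gm5506 at 8.37 against 0.311. Lower genes were Trim12a at 0.112 against 6.56, Tnnt3 at 0.857 against 6.76, Ckm at 0.715 against 6.13, Tnnc2 at 0.577 against 5.27, Cdcp1 at 5.73 against 21.0, Nktr at 6.47 against 22.6, Srrm2 at 10.3 against 34.1 and Pip at 4.10 against 13.8. In total 175 genes were higher and 221 lower, but 101 and 384 with a common sum and 89 and 617 with a common sum without milk proteins, which shifted the median over all genes by -0.15 and -0.27. Among protein-coding genes 126 were higher and 104 lower. Against Ezh2 KO, 5 of 15 milk protein genes were higher (median 0.87), with Lalba at 3153 against 717, and transport genes were higher, 5 of 10 (median 1.06). Igj was at 113 against 10.8, Cd79a at 8.70 against 0.319, Cd79b at 7.48 against 0.856, Marco at 5.09 against 0.274, Nov at 31.7 against 5.94, Ppapdc1a at 5.73 against 0.340 and 2010001M09Rik at 8.06 against 0.985. Of 5 erythroid genes 4 were lower (median -4.24), namely Hbb-b1 at 3.48 against 160, Hba-a1 at 50.4 against 985, Alas2 at 4.25 against 98.4 and Hbb-b2 at 12.9 against 204. Lower too were Beta-s, a globin gene outside that list, at 154 against 3376, Ucp1 at 1.82 against 32.4 and Cyp1a1 at 0.223 against 7.77. That comparison had 165 genes higher and 200 lower, but 82 and 713 with a common sum (shift -0.40), 106 and 349 without milk proteins in the sum (shift -0.21) and 105 and 355 without milk, muscle and erythroid genes (shift -0.22). Among protein-coding genes 119 were higher and 109 lower.

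**Figure D2:**
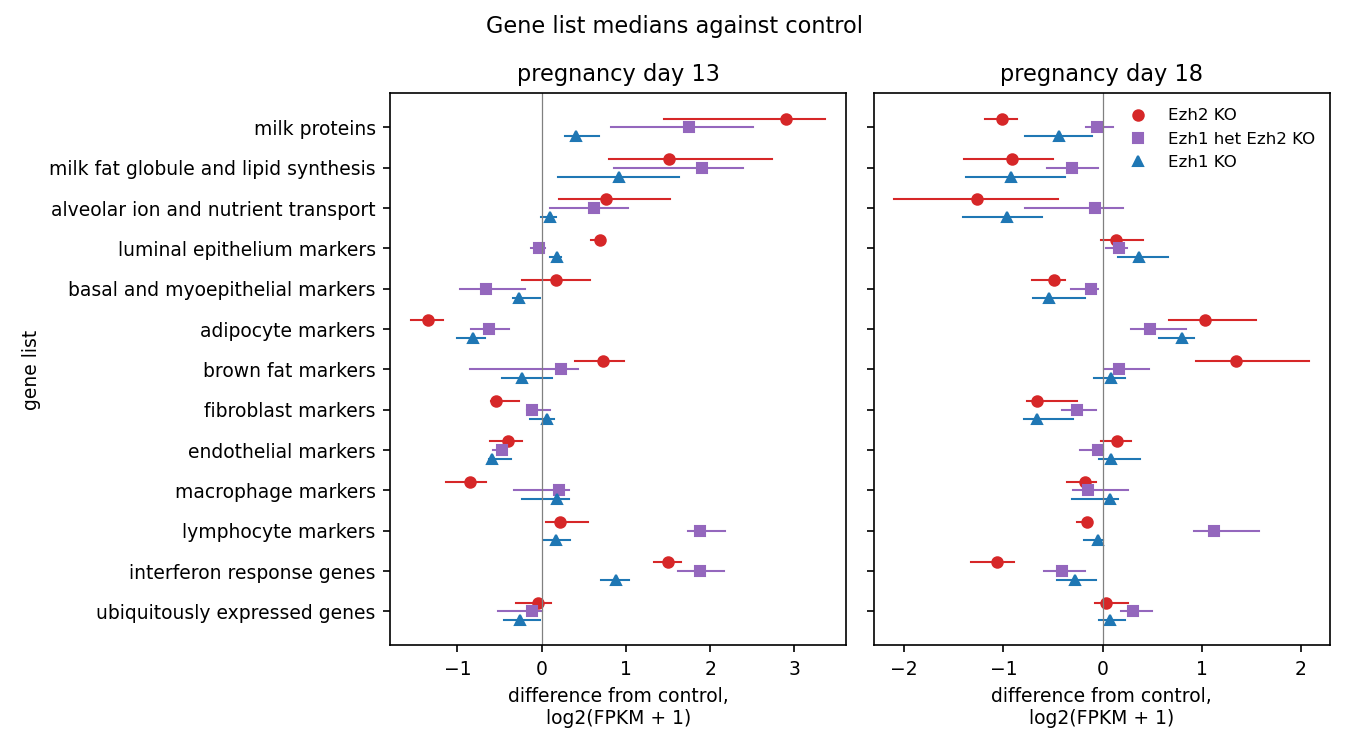
Median difference from control in log2(FPKM + 1) for 13 gene lists at p13 and p18, with symbols for the 3 genotypes and lines for the quartiles over the members of a list, which are not an error of the median. The milk protein median in Ezh2 KO is 2.90 at p13 and -1.01 at p18.

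The difference between the Ezh2 KO effects at the 2 stages, p18 minus p13, was negative for 13 of 15 milk protein genes past the threshold (median -3.82), for 13 of 15 milk fat and lipid genes (median -2.45) and for all 12 interferon response genes (median -2.67). Lao1 had a difference of -6.44, Lalba -5.90, Glycam1 -5.79, Cidea -5.78, Wap -5.09, Slc34a2 -5.02, Csn1s2a -4.77 and Pigr -4.66. It was positive for all 13 adipocyte markers (median 2.78), all 12 muscle markers (median 6.50) and 4 of 5 erythroid genes (median 6.82), with Sfrp5 at 7.25, Hbb-b1 at 8.43, Beta-s at 7.28, Hba-a1 at 7.12, and the muscle genes Acta1 at 7.83, Actn3 at 7.12, Myh4 at 7.10 and Atp2a1 at 6.93. In total 1550 genes had a positive and 856 a negative difference. With a common sum these were 2545 and 487 (shift of the median over all genes 0.33), and with a common sum without milk proteins 1310 and 1143 (shift -0.14).

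In virgin glands without prolactin, some milk protein genes were higher in Ezh2 KO than in control: the casein genes Csn1s1 and Csn2 stood at 60.4 against 0.932 FPKM and 12.5 against 0.443, and Lalba at 7.46 against 0.256. Of 15 milk protein genes 7 were higher and 1 lower (median 0.53). Fabp3, a fatty acid binding protein gene, was at 109 against 0.734. Brown fat markers were higher, 5 of 6 (median 2.44), with Ucp1 at 210 against 2.003. Of 12 luminal markers 3 were lower (median -0.78), with Krt8 at 152 against 322, and of 14 regulators of the alveolar lineage 4 were lower (median -0.63), with Tnfsf11, which encodes RANKL, at 1.77 against 30.7 and the prolactin receptor gene Prlr at 29.8 against 70.4. All 14 lymphocyte markers were higher (median 3.23), with Cd79a at 60.9 against 1.63 and Faim3 at 23.8 against 0.450, as were 10 of 18 proliferation genes (median 1.05) and Glycam1 at 743 against 13.7. Gdpd3 was at 28.0 against 0.640 and the agouti gene at 35.2 against 0.242. Other low genes were Calca at 2.81 against 66.8, Abp1 at 1.18 against 33.7, Defb1 at 3.75 against 58.1, Mup10 at 56.4 against 679, Dmbt1 at 6.67 against 78.8, Sprr1a at 1.28 against 12.5 and Cyp3a57 at 1.80 against 12.3. In total 478 genes were higher and 130 lower.

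After prolactin, 6 of 15 milk protein genes were higher and 2 lower in Ezh2 KO than in control (median 0.18), with Csn1s1 at 121 against 16.3 FPKM, Csn2 at 79.4 against 19.2 and Lalba at 13.3 against 0.434. Their share of the summed FPKM was 0.149% against 0.292%, a share that includes Glycam1 at 2.10 against 864. Without prolactin the shares were 0.248% in Ezh2 KO and 0.106% in control, with Glycam1 at 743 against 13.7. Ezh2 KO glands also had higher brown fat markers, 5 of 6 (median 1.98), and luminal markers had a median of -0.68 with none of 12 past the threshold. Fabp3 was at 107 against 19.6, Cidea at 307 against 59.6, Gdpd3 at 25.05 against 0.664, Amtn at 11.7 against 0.149, Gchfr at 14.3 against 0.906 and the agouti gene at 62.4 against 0.724. The lymphocyte markers took the opposite direction, with all 14 lower (median -3.36): Cd79a was at 0.383 against 49.7, Cd79b at 0.555 against 48.3, Ccr7 at 0.292 against 21.0, Ms4a1 at 0.0929 against 16.8, Faim3 at 0.121 against 20.5 and Ptprcap at 1.32 against 35.1. Glycam1 was at 2.10 against 864 and Calca at 6.93 against 135. In total 109 genes were higher and 387 lower.

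Prolactin addressed the acute response of the gland to the hormone that drives STAT5. In both genotypes the negative feedback genes of cytokine signalling were higher afterwards: in control Socs3 went from 5.597 to 80.2 FPKM and Cish from 6.64 to 62.3, and in Ezh2 KO Socs3 from 6.17 to 58.8 and Cish from 11.0 to 51.1. Of 11 STAT5-responsive genes 6 were higher in control (median 1.78) and 5 in Ezh2 KO (median 0.83). Glucocorticoid-induced genes were higher in 9 of 12 cases in control (median 1.82) and 10 of 12 in Ezh2 KO (median 2.13). The metallothionein genes Mt1 and Mt2 reached 5688 and 5677 in control from 259 and 133, and 3528 and 3609 in Ezh2 KO from 185 and 121, and Fkbp5, a glucocorticoid receptor cochaperone, reached 158 in both from 11.8 and 11.2. Acute phase and inflammation genes were higher, 8 of 10 in control (median 1.56) and 7 of 10 in Ezh2 KO (median 1.62), with the neutrophil gene S100a9 at 90.6 against 3.46 and 182 against 10.3. Immediate early genes had medians of 0.58 and 0.36, with 3 and 4 of 13 higher, and circadian clock genes medians of -0.09, where the mean was 0.08, and 0.29. Saa3 was at 46.8 against 1.38 in control and 34.6 against 5.55 in Ezh2 KO, and Retnlg at 27.9 against 1.83 and 50.8 against 1.18. The endothelial selectin gene Sele was at 6.03 against 0.412 in control and 24.7 against 0.2996 in Ezh2 KO, and Selp at 20.1 against 2.06 and 67.1 against 3.61. Acta1 was at 273 against 13.0 in control and 431 against 8.46 in Ezh2 KO, and Ucp1 in control was at 67.8 against 2.003. Lower genes in control were B3galt2 at 4.51 against 58.6, Ckm at 0.291 against 8.13, Tnnt3 at 0.354 against 7.56, Cd248 at 8.30 against 50.9, Irs3 at 2.25 against 17.0, Spon2 at 2.13 against 15.6, Cd209f at 8.72 against 50.05 and Adrb3 at 18.2 against 99.8. In Ezh2 KO the lowest were lymphoid genes and Glycam1: Cd79a, Cd79b, Ms4a1, Faim3, Ccl22 at 0.321 against 28.2, Ccl5 at 12.0 against 277 and Apol7c at 0.0187 against 19.6. All 14 lymphocyte markers were higher after prolactin in control (median 2.96) and lower in Ezh2 KO (median -3.53). In total 679 genes were higher and 245 lower in control, and 392 higher and 582 lower in Ezh2 KO. With a common sum these were 626 and 455, and 322 and 954, with shifts of the median over all genes of -0.15 and -0.17. Without milk proteins in the sum they were 531 and 364, and 285 and 769, and without milk, muscle and erythroid genes 530 and 365, and 285 and 769. With a pseudocount of 5 the majority in Ezh2 KO turned, to 232 higher and 198 lower.

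**Figure D3:**
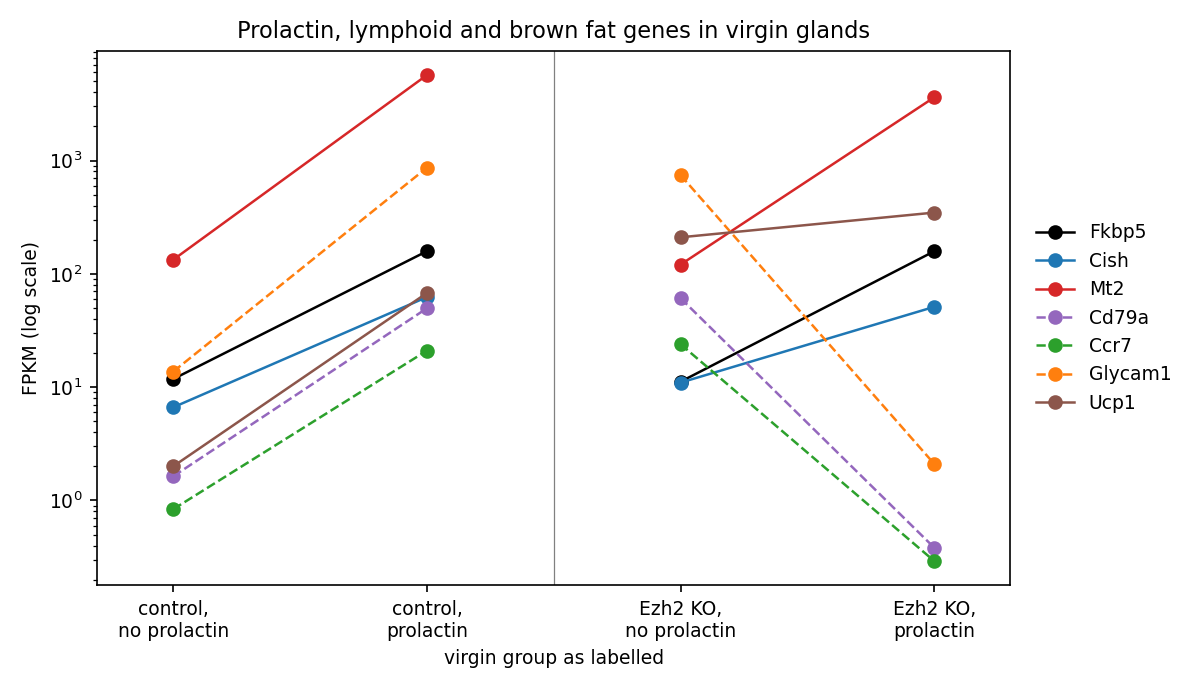
FPKM on a log axis for 7 genes in the 4 virgin groups, with lines joining the groups before and after prolactin of one genotype, dashed for lymphoid genes and Glycam1, and 1 pooled value per point without error bars. Fkbp5 is near 158 after prolactin in both genotypes, while Cd79a is at 49.7 in control and 0.383 in Ezh2 KO.

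The response to prolactin in Ezh2 KO minus that in control was negative past the threshold for 789 genes and positive for 94. The lowest were Glycam1 at -13.78, Cd79a at -9.75, Cd79b at -8.79, Faim3 at -8.36, Ms4a1 at -7.89, Ccr7 at -7.85, Ptprcap at -7.54 and Ccl22 at -7.47, and all 14 lymphocyte markers were negative (median -6.46), as were 14 of 18 proliferation genes (median -1.39). The highest were Ctsr at 3.19, Ctsj at 2.31, Sele at 1.99, Abp1 at 1.64, Gpr81 at 1.54, Cyp2b10 at 1.52, Clstn3 at 1.44 and Ifitm6 at 1.40. For the glucocorticoid-induced list the median difference was 0.13 with none of 12 past the threshold, and for the STAT5-responsive list it was -0.33 with 3 of 11 negative.

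The genotype comparisons were then set against each other across 14273 genes. At p13, 196 genes were higher in both Ezh2 KO and Ezh1 het Ezh2 KO against control, where independent lists would share 11.8, and 391 were lower in both, against 30.03, with Pearson r = 0.77, Spearman rho = 0.64 and a covariance of 0.38. The independent number is the product of both counts over the genes compared. These pairs share the control column, part of the excess may come from it, and unchanged groups could not be simulated without replicates. Without a shared group, Ezh2 KO against control and Ezh1 het Ezh2 KO against Ezh1 KO gave r = 0.39 and rho = 0.19 at p13, and r = 0.0023 and rho = -0.035 at p18. Both p13 differences subtract a group with muscle RNA, with muscle markers at 1.56% of the sum in control and 0.400% in Ezh1 KO. In Ezh2 KO and Ezh1 het Ezh2 KO these markers made up 0.00258% and 0.00358%, so muscle genes may raise the p13 r. At p18, 74 genes were higher in both groups against control, where independent lists would share 4.17, and 93 were lower, against 4.74 (r = 0.57, rho = 0.65, covariance 0.19). For Ezh2 KO and Ezh1 KO against the same control, r was 0.57, rho 0.63 and the covariance 0.24 at p13, with 84 genes higher and 301 lower in both against 7.95 and 21.4. At p18 r was 0.66, rho 0.76 and the covariance 0.19, with 85 higher and 131 lower against 4.12 and 4.24. The Ezh2 KO differences at p13 and p18, which share no group, had r = -0.18 and rho = -0.28, with 47 genes higher and 29 lower at both stages, where independent lists would share 9.004 and 20.2, 80 higher at p13 and lower at p18, and 172 the other way. The Ezh2 KO differences of virgin glands without and after prolactin, which share no group and were paired after their values were seen, had r = -0.11 and rho = 0.059. By the design both come from the same mice, so differences between single mice can enter both. For this pair 47 genes were higher and 42 lower in both, against 3.65 and 3.52, while 246 were higher without and lower after prolactin and 10 the other way. The prolactin differences of control and Ezh2 KO had r = 0.14 and rho = 0.39, with 256 genes higher and 93 lower in both, against 18.6 and 9.99, while 210 were higher in control and lower in Ezh2 KO and 8 the other way. Genes are not independent replicates, and these correlations describe the pooled values.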

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

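In this part, all tests except the p18 rescaling without the milk list were chosen after the patterns they bear on were seen. The bounds of the p13 rescaling and of the lymph node test were set before the values they measure were seen.

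Some lists had medians on opposite sides of control under the same contrast, each by at least 0.58 on the log2 scale. None of these differences was tested, because each group has 1 value. Between p13 and p18, the Ezh2 KO median went from 2.90 to -1.01 for milk proteins (difference -3.91), from 1.52 to -0.91 for milk fat and lipid synthesis (-2.43), from 0.77 to -1.26 for alveolar transport (-2.03), from -1.35 to 1.04 for adipocyte markers (2.39), from -2.35 to 4.50 for erythroid genes (6.85) and from 1.497 to -1.06 for interferon response genes (-2.56). The Ezh1 KO median went from 0.92 to -0.92 for milk fat and lipid synthesis (-1.84), from -0.81 to 0.81 for adipocyte markers (1.61), from -2.14 to 1.52 for skeletal muscle markers (3.66) and from -0.93 to 2.11 for erythroid genes (3.04). For lymphocyte markers, the prolactin median was 2.96 in control and -3.53 in Ezh2 KO (-6.50), and the Ezh2 KO median was 3.23 without and -3.36 after prolactin (-6.59).

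The first pattern is the higher milk genes of the p13 Ezh2 KO group. A larger share of epithelium as the sole cause is argued against by a milk protein median 2.20 above the luminal marker median. The luminal marker median was itself above control, so a larger share may contribute in part. A loss of fat that lifts all other cell types is argued against by a median of -0.54 over the fibroblast, endothelial and macrophage lists. For dilution by muscle and blood RNA in the control, the milk protein median was 2.97 after rescaling without the milk, muscle and erythroid lists. That rescaling could hardly have lowered it, since the muscle and erythroid lists held only 1.56% and 0.307% of the p13 control sum. The listed genes are too small a share to account for the difference, but RNA of other muscle and blood genes was not removed. Loss of Ezh2, which the FPKM of the gene itself does not check, may contribute. Ezh1 het Ezh2 KO exceeded Ezh1 KO by a median of 1.19, a comparison without the control. Those groups also differed in Ezh1, at 6.17 against 1.06 FPKM, and in muscle markers, at 0.00358% against 0.400% of the sum. The 1.19 therefore does not isolate Ezh2. Different timing of pregnancy between the mice may equally contribute. Ezh2 KO minus Ezh1 KO at p13 followed control p18 minus p13 across genes (r = 0.38, rho = 0.47). Both differences include a fall of muscle RNA, which may add to r. With 1 pooled value per group, loss of Ezh2 and different timing are not separated. A larger share of alveolar cells within the epithelium stays open too. Both pregnant control groups also had 3 genes, Gm5506, Gm8580 and BC002163, more than 3-fold below every other group. Whether the control mice of either stage differed in more than the labels state was not tested.

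The second pattern is the lower milk genes of the p18 Ezh2 KO group. Less epithelium in the sample is argued against by a luminal marker median 1.14 above the milk protein median. For scaling by milk RNA, the milk protein median was -1.09 after rescaling without the milk list. That rescaling could hardly have closed the gap, since it shifted the median over all genes by only -0.058. It shows only that this scaling does not account for the gap. A common sum instead shifted the median over all genes by 0.22, which is toward a smaller gap. The summed FPKM was 787794 in Ezh2 KO and 980997 in control. Milk genes of high FPKM shift by more than 0.22, since the pseudocount damps the shift of low genes. Loss of Ezh2 by itself stays open, because the Ezh1 het Ezh2 KO group, labelled with the same deletion, had a median of -0.056 against control but also lacks an Ezh1 allele and is 1 pooled value. A difference in pregnancy timing and variation between mice stay open too and were not tested.

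The third pattern is the crossing of lymphocyte markers and Glycam1 in the virgin glands. A prolactin response that depends on genotype, or an Ezh2 effect that depends on prolactin, stays open, because the gaps of -6.50 and -6.59 between the medians only restate the crossing. Labels exchanged across prolactin states are argued against by the glucocorticoid-induced list, whose median was higher after prolactin in both genotypes (smaller median 1.82), whereas genotype labels exchanged within 1 prolactin state stay open, since the brown fat list median (smaller median 1.98) and 47 genes, Gdpd3 and agouti among them, were higher in Ezh2 KO both times and 42, with Calca, lower both times, but 246 and 10 lay on opposite sides and nothing here says which differences last. Lymph node tissue in some glands is a candidate explanation that stays open: a median of 10 lymph node genes was 2.40 higher in Ezh2 KO without prolactin and -2.28 after it (smaller shift 2.28; 2.44 and -2.57 without the uncertain Ccl21a), but 6 of the 10 are B cell genes, so that median largely restates the crossing, and of the vessel genes, all low, Chst4 (1.24 against 0.0485 FPKM without prolactin, 0.0384 against 1.06 after) and Fut7 (1.61 against 0.226, 0.119 against 0.752) crossed while Madcam1 (1.59 against 0.566, 1.24 against 1.55) did so by less. The labels' protocol states removal of the lymph node for the untreated gland and does not mention it for the gland taken after prolactin, and Glycam1 is also made by lymph node vessels.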

How the results depend on the processing

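The threshold of 2, the protein-coding setting and the sum without milk, muscle and erythroid genes were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers. Fits by stage, limma without a trend, leaving out replicates and an estimated correlation for lists were not run, since each group has 1 value, and depth is unknown. Some small medians changed sign under a rescaling, of which the farthest from 0 was that of the PRC2 list for control p18 against p13, at -0.47, which came to 0.007 with a common upper quartile. Under the alternatives 3011 list medians moved by less than 1.5-fold and 61 by more, 1084 values of named genes by less and 260 by more, and 87 correlations by less than 0.1 and 1 by more. Of the counts, 109 stayed within 1.5 times and 51 did not.

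The counts that moved further follow, in the order p13 Ezh2 KO, Ezh1 KO, Ezh1 het Ezh2 KO against control and Ezh1 het Ezh2 KO against Ezh2 KO, the same at p18, prolactin in control, prolactin in Ezh2 KO, their difference, virgin Ezh2 KO without and after prolactin, control p18 against p13, control p13 against virgin, and the difference of the Ezh2 KO effects. A pseudocount of 5, which shrinks differences of low genes by construction, gave 674, 334, 436, 216, 344, 196, 182, 201, 425, 430, 426, 231, 207, 1659, 852 and 1354. A threshold of 2, which counts fewer genes by construction, gave 308, 211, 294, 109, 154, 109, 117, 112, 205, 252, 393, 179, 159, 780, 585 and 721. A pseudocount of 0.1, which enlarges differences of low genes, gave 1437 and 957 for the p13 Ezh1 het Ezh2 KO comparisons, 1073, 679, 890 and 711 at p18, 1488, 1548 and 1330 for prolactin and 1050 and 817 for virgin Ezh2 KO. Protein-coding genes alone, a smaller set, gave 394 for p13 Ezh1 KO and 226, 230 and 228 for p18 Ezh1 KO, Ezh1 het Ezh2 KO against control and against Ezh2 KO. A common sum gave 795 for p18 Ezh1 het Ezh2 KO against Ezh2 KO and 6835 for control p18 against p13. For p18 Ezh1 het Ezh2 KO against control, the common sum without milk proteins gave 706, and that without milk, muscle and erythroid genes 706 too. The cause was not tested for the common sums. With a pseudocount of 5, the STAT5-responsive median after prolactin in control was 1.05 and the correlation of the prolactin differences was 0.25.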

Other observations

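The genes in this part were chosen after their values were seen. Ucp1, the uncoupling protein of brown fat, was higher in Ezh2 KO than in control at every stage. It was at 210 and 347 FPKM in virgin Ezh2 KO without and after prolactin against 2.003 and 67.8 in control, at 65.5 against 0.499 at p13 and at 32.4 against 0.964 at p18. In Ezh1 het Ezh2 KO it was at 1.88 at p13 and 1.82 at p18.

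The agouti gene, a coat colour gene, was in control glands at 0.242 FPKM in virgins without prolactin, 209 at p13 and 857 at p18, and at 213 in Ezh1 KO, 353 in Ezh2 KO and 362 in Ezh1 het Ezh2 KO at p13, and 391, 441 and 904 in the same groups at p18. Fasn was at 39.9 in the p13 control and between 299 and 772 in the other p13 groups, and Thrsp at 108 against 695 to 1515. Lars2 was at 574 in the p13 control, 489 in Ezh2 KO, 164 in Ezh1 KO and 39.1 in Ezh1 het Ezh2 KO. Gdpd3 was at 28.0 and 25.05 in the virgin Ezh2 KO groups and at 6.49 or less in all others. BC018473 was at 81.1 in p18 Ezh2 KO and at 1.52 or less in every other group.

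A list of 12 liver genes, assembled after some of them were seen, had a median 3.47 above control in p13 Ezh1 KO and 1.33 above control in virgin Ezh2 KO without prolactin, against 0.62 or less in the other genotype comparisons with control.

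Gm5506, Gm8580 and BC002163 were each more than 3-fold lower in both pregnant control groups than in every other group. Gm8580 was at 1.03 and 1.13 FPKM there, and BC002163 at 0.836 and 0.918. Of the other 15 pairs of a p13 and a p18 group, 14 had 0 such genes and 1 had 1 gene, Snora52.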
